A study of Homo sapiens with 18 samples.

How the data were processed

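Small RNA was sequenced from HEK293T cells, a human embryonic kidney line, and from the extracellular vesicles (EVs) those cells released during 24 h without serum. Cells and vesicles came from wild type cultures and from 1 ATG7-/- and 1 ATG12-/- clone. ATG7 and ATG12 act in the pathway that attaches LC3 and its relatives to membrane lipids. The 18 libraries form 6 groups of 3, which the labels call biological replicates. Per the labels' protocols the libraries were made with a SMARTer kit over 12 PCR cycles and read as single 50 bp reads on 2 lanes. This kit adds a poly(A) tail and copies RNA by template switching.

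The deposited table holds 1 value per feature and library for 2462 features. Per the submitters' processing notes, cutadapt 2.3, Bowtie2 2.3, bedtools and DESeq2 were used, with the builds GRCh38 and hg38. The order of these steps, the annotation and any filter are not stated. The unit of the deposited values is a scaled signal: within each library 100.0% of the values were whole multiples of the smallest value, within a tolerance of 1e-06 of a multiple. Median-of-ratios factors recomputed from those multiples over all 18 libraries matched the inverse of the step sizes. The multiples were therefore taken as whole reads and the deposited values as reads divided by 1 size factor per library, called normalised reads from here on. One read equals between 0.477 and 1.89 normalised reads, depending on the library.

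The recovered reads assigned to features numbered 1188388 to 1804089 per cell library and 1881080 to 3382605 per vesicle library. The depths of vesicles and cells do not overlap. Copies of 1 RNA often hold nearly the same reads. How reads that match several copies were counted is not stated, so these totals can exceed the number of reads sequenced. Counting error alone understates the spread of shares and counts, and PCR copies are not independent molecules. Within a group, replicate pairs differed by 5.56 to 91.4 times the counting noise (chi-square per degree of freedom). Pearson's r between replicates on the log2 scale was 0.981 to 0.994, across features. No replicate was a copy of another.

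Features are named as in the table. GENCODE release 29 placed 1682 of them, RefSeq GRCh38.p14 placed 26 more, and both use the GRCh38 build. Of the older names, 383 were matched to a current symbol by a listed synonym and 30 by their number, 415 in all with the 2 whose synonym is shared. The table holds 268 C/D box small nucleolar RNAs (snoRNAs), 108 H/ACA box snoRNAs, 24 small Cajal body RNAs (scaRNAs), 1425 microRNAs and 622 tRNA genes. It also holds 5 spliceosomal snRNAs, 4 Y RNAs, 4 vault RNAs, U7 snRNA and the telomerase RNA. 7SL, 7SK, ribosomal RNA and piRNA are not analysed here, and neither are the ATG7 and ATG12 mRNAs, so the knockout labels cannot be checked against the genes they name.

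The main test was chosen for the unit found. The design written before the data were examined assumed raw counts and edgeR's quasi-likelihood test. Because the deposited values are scaled, the main test is limma's moderated test with an intensity trend on log2 (normalised reads + 1), limma 3.58.1 in R 4.3.3. A feature was tested when its value reached 10 in at least 3 of the fitted libraries. Vesicle comparisons were fitted over the 9 vesicle libraries, cell comparisons over the 9 cell libraries, and comparisons between vesicles and cells over all 18. Adjusted p-values are limma's, with Benjamini-Hochberg adjustment over all features tested in a comparison, and a call is an adjusted p under 0.05. Every log2 fold change is followed by its standard error (SE). All tests are two-sided.

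Lists of RNAs were tested with camera on the same log2 values, with a preset correlation of 0.01, and again with a correlation estimated from the data. fry tested whether a list moves one way on balance. Adjusted list p-values cover the lists of 1 comparison. The lists fixed before the data were examined were the classes above, all snoRNAs with scaRNAs, the snoRNAs hosted by GAS5, RPL13A and SNHG1, snoRNAs that act in cleavage of the ribosomal RNA precursor, the let-7 family, the miR-17-92 cluster with its paralogs, microRNAs known from serum, blood and liver, microRNAs linked to the RNA-binding protein YBX1, tRNA isotypes known to give 5-prime fragments, other tRNA isotypes, and the snoRNAs and microRNAs of the imprinted regions 14q32 and 15q11. None of the imprinted lists had a tested member in vesicles or in cells. The cleavage list holds 5 copies of U3, so U3 weighs 5 times in its medians, counts and p-values. Groups of tRNA genes by isotype were formed after the data were examined. Shares of reads per class were compared with an exact permutation test, whose smallest possible p is 0.1 for 3 against 3 libraries and 0.0119 for 6 against 3.

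The features the text may name come from a rule fixed before the data were examined: the 10 called features with the largest fold in each direction whose groups do not overlap and whose higher group averages at least 50, up to 4 called members of each list, and every Y, vault and telomerase RNA. The level was to be read as CPM and is read here as normalised reads. The rule picked 602 feature and comparison pairs, of which 266 were taken into the text after their values were seen. Both totals are given again where the effect of the processing is described, so that the choice can be weighed.

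The test was tried on simulated reads with 200 changed features. The changes were balanced between higher and lower and each feature was drawn independently. In the real libraries whole classes move 1 way and copies share reads, so these rates may not hold there. In ATG7-/- against wild type vesicles, with 850 features, it recovered 46.3% of 1.5-fold, 73.1% of 2-fold and 97.0% of 4-fold changes, and 2.70% of its calls were false. In ATG7-/- against wild type cells, with 853 features, it recovered 40.3%, 94.0% and 100.0%, with 1.89% false. In wild type vesicles against cells, with 905 features, it recovered 56.7%, 92.5% and 97.0%, with 4.09% false.

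The alternatives chosen before the data were examined were the DESeq2 1.42.0 Wald test on recovered reads, median-of-ratios factors of the fitted libraries, library totals alone, TMM factors from microRNAs alone, no filter, a minimum value of 50, copies of 1 RNA summed, the replicate number as a block, 1 fit over all 18 libraries, an estimated correlation and leaving out each library in turn. Chosen after the data were examined were TMM factors under the main test, pseudocounts of 0.5 and 10, and each mature tRNA counted once in the shares. The quasi-likelihood test of edgeR 4.0.16 with TMM factors (filterByExpr, minimum count 10) was the main test planned beforehand. It was run on recovered reads and became an alternative after the data were examined. TMM factors from microRNAs hold most microRNAs near no change by construction, so they cannot check a change of the microRNAs as a class. Correlations across snoRNAs used 100000 permutations and 2000 bootstrap resamples. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

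The p-values measure the spread between these libraries, which come from 1 wild type line and 1 clone per knockout. A difference between clones and a difference between genotypes cannot be told apart in this design.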

Results

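Small RNAs were measured in vesicles and in cells of wild type, ATG7-/- and ATG12-/- HEK293T cultures after 24 h of serum starvation, with 3 libraries in each of the 6 groups. Cell libraries held 1188388 to 1804089 reads assigned to small RNA features and vesicle libraries 1881080 to 3382605. Values are normalised reads, the deposited reads divided by 1 size factor per library. Fold changes are on the log2 scale with their standard error (SE), and adjusted p-values are from limma over all features of a comparison. For lists, adjusted p is from camera with its preset correlation and estimated adjusted p is from camera with the correlation estimated from the data. List-alone counts are calls adjusted over the list alone. Where leaving out a library ends or makes a call, the library is named with the value without it. SnoRNAs guide the chemical modification and cleavage of ribosomal RNA in the nucleolus.

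Wild type vesicles were first set against the cells that released them, to ask which small RNAs are relatively more abundant in the vesicles. The vesicles were poor in C/D box snoRNAs and rich in tRNA, U1 and U3. C/D box snoRNAs took 22.2% ± 3.05 of the reads in wild type vesicles and 61.4% ± 2.53 in wild type cells (SD, n = 3 each). tRNA took 50.0% ± 6.01 in vesicles and 24.0% ± 2.03 in cells, and spliceosomal snRNAs 8.11% ± 0.534 and 2.52% ± 0.118. The smallest p an exact permutation test can give for 3 against 3 libraries is 0.1, which each of these differences reached. With each mature tRNA counted once, tRNA took 27.2% of reads in vesicles and 13.9% in cells. The other shares given here count every tRNA gene. microRNAs took 15% ± 2.67 in vesicles and 2.15% ± 0.153 in cells, and 1 annotated microRNA, miR-6724-5p, made up 14.7% ± 2.63 in vesicles and 0.781% ± 0.0665 in cells. The annotated copies of miR-6724 lie in the ribosomal RNA repeats of chromosome 21, so its reads cannot be separated here from ribosomal RNA. All other microRNAs together took 0.335% ± 0.0333 of the reads in vesicles and 1.37% ± 0.102 in cells.

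Of 905 features tested, 352 were higher in wild type vesicles than in cells, 388 were lower and 165 were not called. The groups did not overlap for 758 features, 83.8% against 10% by chance. With library totals as the scaling the median of all features moved by -1.51 and 19.4% of calls were higher, against 47.6%, and TMM factors from microRNAs moved the median by 0.23. Among the C/D box snoRNAs the change was -6.56 (SE 0.16) for HBII-99B (SNORD12B, in ZFAS1), -6.41 (SE 0.19) for U77 and -6.28 (SE 0.23) for U76. It was -6.35 (SE 0.31) for U28, -6.24 (SE 0.23) for HBII-240 and -6.23 (SE 0.23) for Z17B. U52 (-6.08, SE 0.16), U44 (-5.76, SE 0.14), U31 (-5.44, SE 0.17), U27 (-5.29, SE 0.15) and U34 (-5.13, SE 0.14) followed. miR-3607-5p (-6.65, SE 0.19) and miR-3653-5p (-6.09, SE 0.21), whose annotated loci lie on snoRNA sequence, fell with them. U3, the snoRNA that guides early cleavage of the ribosomal RNA precursor, was higher in vesicles by 3.07 (SE 0.18). U22 (3.70, SE 0.24) and the H/ACA box snoRNAs ACA63 (6.15, SE 0.18), U67 (2.26, SE 0.20), ACA10 (2.00, SE 0.18) and ACA21 (0.95, SE 0.21) were also higher, ACA21 reversing to -0.57 with library totals.

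U1 was higher in wild type vesicles than in cells by 4.26 (SE 0.16) and the telomerase RNA hTR by 4.12 (SE 0.20). U5 (1.5, SE 0.17), U6 (1.48, SE 0.18) and U2 (0.66, SE 0.16) were higher as deposited and fell below 0 with library totals. Single tRNA genes were among the highest: Val-AAC-1-1 by 5.83 (SE 0.15), Glu-TTC-4-2 by 5.0 (SE 0.21), Glu-CTC-1-2 by 4.52 (SE 0.18) and Ser-TGA-2-1 by 4.11 (SE 0.14). Copies of 1 tRNA hold nearly the same reads, so a named copy stands for its group. RNY4 (1.31, SE 0.15) and RNY5 (1.87, SE 0.19) were higher, and RNY1 (-0.93, SE 0.16) and RNY3 (-1.22, SE 0.15) lower. With library totals RNY4 turned to -0.21 and the call of RNY5 was lost. The vault RNAs VTRNA1-1 (-0.94, SE 0.18) and VTRNA1-3 (-1.47, SE 0.20) and U7 snRNA (-2.03, SE 0.18) were lower, and VTRNA1-2 (-0.06, adjusted p = 0.776) was called only with library totals, as lower. miR-6724-5p was higher by 5.74 (SE 0.18), and let-7a-5p (-1.21, SE 0.15) and let-7e-5p (-1.89, SE 0.24) were lower. miR-92a-3p was higher by 0.70 (SE 0.15) as deposited and stood at -0.82 with library totals. miR-486-5p, abundant in blood, was higher by 3.85 (SE 0.34). miR-223-3p was listed at 0 in every wild type cell library and miR-150-5p had 1 read in all of them, so no fold is given.

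As lists, C/D box snoRNAs had a median of -3.68 in wild type vesicles against cells (150 tested, 14 higher, 125 lower, list-alone 15 and 125, camera adjusted p = 1.59e-21, estimated adjusted p = 0.165). All 10 GAS5-hosted snoRNAs were lower (median -5.08, adjusted p = 2.26e-05, estimated adjusted p = 0.239), as were all 4 hosted by RPL13A (median -3.72, adjusted p = 0.0158, estimated adjusted p = 0.239). The SNHG1 list, which holds U22, was lower for 6 of 8 members (median -3.57, adjusted p = 0.0478, estimated adjusted p = 0.368). tRNA had a median of 0.51 (489 tested, 255 higher, 148 lower, list-alone the same, adjusted p = 1.7e-09, estimated adjusted p = 0.165), turning to -0.94 with library totals. Isotypes known for 5-prime fragments stood at 1.17 (adjusted p = 8.06e-06, estimated adjusted p = 0.239) and -0.30 with library totals, and other isotypes at 0.30 (adjusted p = 0.00299, estimated adjusted p = 0.369), also negative with library totals. H/ACA box snoRNAs (median -1.04, adjusted p = 0.152, 30 higher, 58 lower), let-7 (-1.34, adjusted p = 0.176), miR-17-92 (-0.54, adjusted p = 0.735), and snRNAs (1.48, adjusted p = 0.185, -0.03 with library totals) were not called. Nor were Y RNAs (0.19, adjusted p = 0.782), vault RNAs (-0.94, adjusted p = 0.462), cleavage snoRNAs (2.54, adjusted p = 0.0775) and the serum and blood microRNAs (adjusted p = 0.0787). The scaRNAs had a median of -0.31 and a mean of 0.18, and microRNAs a median of -0.05 and a mean of 0.14, and neither list was called. The medians of microRNAs and Y RNAs changed sign with the scaling.

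**Figure D1:**
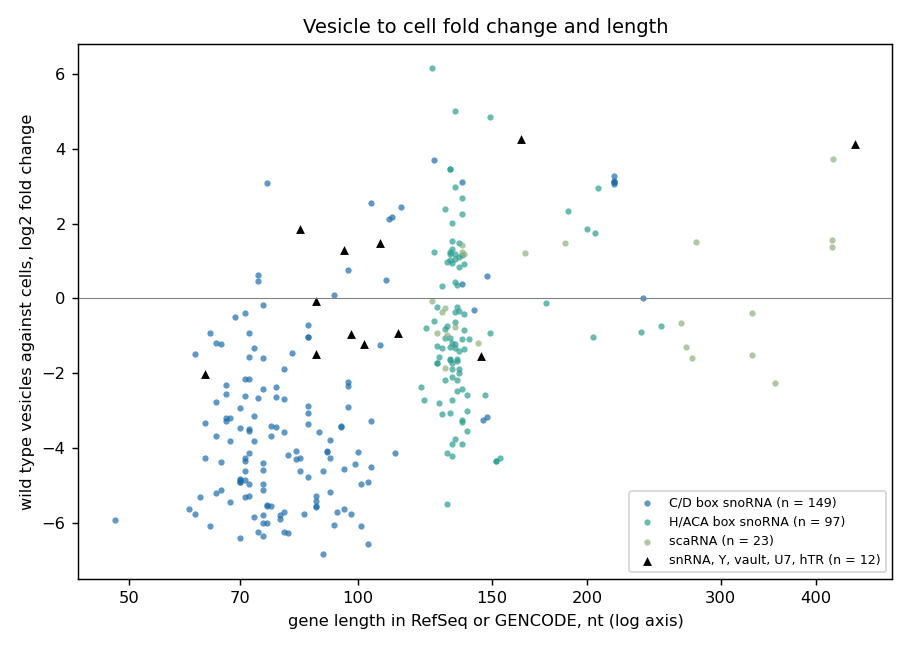
Change between wild type vesicles and cells (log2 fold change, vertical axis) of each snoRNA, scaRNA, snRNA, Y, vault, U7 and telomerase RNA against gene length (nt, log axis). C/D box snoRNAs of up to 70 nt had a median of -3.80 (31 genes) and those over 140 nt a median of 1.83 (10 genes, 5 of them copies of U3). With U3 counted once the median over 140 nt was -0.14 (6 genes).

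Vesicles of ATG7-/- cells were compared with wild type vesicles, the central question of the design, whether small RNA release depends on the LC3 conjugation genes. Called lower were 117 of 140 C/D box and 88 of 92 H/ACA box snoRNAs, and called higher 241 of 467 tRNA genes. With an estimated correlation neither box type was called as a list (adjusted p = 0.0728 and 0.0781), and the tRNA median of 0.47 came down to 0.092 with library totals. U72 (SNORA72, in an intron of RPL30, chromosome 8, 98042086 to 98042217) went from 1839 ± 194 to 71.2 ± 21.3 normalised reads (SD, n = 3), a change of -4.71 (SE 0.19, adjusted p = 1.43e-09), while the cells held 803.1 ± 93.2 and 886.6 ± 317. ACA16 (SNORA16A, in SNHG12, chromosome 1, 28580920 to 28581053) changed by -4.59 (SE 0.34, adjusted p = 1.7e-07) and ACA62 (SNORA50C, in SNHG25, chromosome 17, 64146339 to 64146471) by -4.58 (SE 0.18). ACA28 (SNORA28, in an intron of EIF5, chromosome 14, 103337849 to 103337974) changed by -4.52 (SE 0.21). tRNA-Glu-CTC-1-2 rose from 111018 ± 5159 to 251397 ± 15796 normalised reads, by 1.18 (SE 0.08, adjusted p = 1.3e-07).

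Of 850 features tested, 285 were higher in ATG7-/- vesicles, 246 were lower and 319 were not called, and the groups did not overlap for 578 features (68%, 10% by chance). With library totals 31.8% of calls were higher, and 29.9% with TMM factors from microRNAs, against 53.7% as deposited. Both scalings moved the median of all features by -0.37, and TMM by -0.12. Also lower were U19 (SNORA74A, -3.63, SE 0.18), U73a (SNORD73A, in RPS3A, -3.59, SE 0.26), ACA37 (SNORA37, in MBD2, -3.50, SE 0.26), U74 (in GAS5, -2.90, SE 0.15) and U35A (in RPL13A, -2.77, SE 0.23). Smaller falls were seen for U67 (-2.03, SE 0.18), U26 (in SNHG1, -1.73, SE 0.16), ACA10 (in RPS2, -1.59, SE 0.14), ACA21 (in RPL23, -1.25, SE 0.16), and U3 (-1.24, SE 0.16), and for U44 (in GAS5, -1.17, SE 0.13) and U34 (in RPL13A, -1.11, SE 0.14). The scaRNAs ACA26 (-2.27, SE 0.18) and ACA47 (-1.14, SE 0.13) fell too. U22 (SNORD22, in SNHG1) went the other way, by 0.73 (SE 0.18, adjusted p = 0.00287), a call lost with library totals and with TMM factors from microRNAs.

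Besides snoRNAs, miR-4485-3p (-4.19, SE 0.33), which matches mitochondrial ribosomal RNA, miR-664b-3p (-3.69, SE 0.27), whose locus is the snoRNA gene SNORA36A, and miR-6724-5p (-1.35, SE 0.16) fell in ATG7-/- vesicles. Among the 37 microRNAs called higher were miR-210-5p (1.96, SE 0.43, adjusted p = 0.00137), miR-210-3p (1.57, SE 0.35), miR-877-5p (1.49, SE 0.23), let-7b-5p (1.30, SE 0.31), miR-342-3p (1.27, SE 0.21) and miR-92a-3p (0.98, SE 0.15). miR-25-3p was called (0.39, SE 0.14, adjusted p = 0.0261), but not with DESeq2, edgeR or any other scaling. Nor was it without replicates 2 or 3 of the wild type or 1 or 2 of the ATG7-/- vesicles (0.27 to 0.39, adjusted p = 0.0607 to 0.129). The blood microRNAs miR-486-5p (1.17, SE 0.21) and miR-150-5p (0.86, SE 0.25) were higher, miR-150-5p not with library totals or TMM factors from microRNAs. miR-223-3p, the only tested member of the YBX1-linked list, was not called in ATG7-/- vesicles (-0.05, SE 0.41, adjusted p = 0.926) or in ATG12-/- vesicles (0.56, SE 0.41, adjusted p = 0.298), and it had no test in cells. tRNA-Gly-CCC-2-2 (1.41, SE 0.11), Glu-TTC-2-1 (1.33, SE 0.12), Tyr-GTA-2-1 (1.30, SE 0.16), Val-AAC-1-1 (1.30, SE 0.13) and Ser-AGA-2-6 (1.09, SE 0.09) rose with Glu-CTC-1-2.

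Among the other polymerase III and small nuclear RNAs, RNY3 (1.24, SE 0.12), RNY1 (1.10, SE 0.13) and RNY4 (0.41, SE 0.10) were higher in ATG7-/- vesicles and RNY5 lower (-0.57, SE 0.12). VTRNA1-2 was higher (0.73, SE 0.13), and like RNY4 lost its call with library totals and with TMM factors from microRNAs. VTRNA1-1 (0.31, adjusted p = 0.0514) and VTRNA1-3 (0.40, adjusted p = 0.0532) were not called, but were at a minimum of 50 or without wild type vesicle replicate 1 (0.34, adjusted p = 0.0317) and 2 (0.49, adjusted p = 0.0381) in turn. hTR (-0.27, adjusted p = 0.223) was called lower only with those scalings and without replicate 2 of the ATG7-/- vesicles (-0.48, adjusted p = 0.0274). U6 was higher (1.03, SE 0.16), and U5 (-1.17, SE 0.16), U2 (-0.56, SE 0.14) and U7 (-0.68, SE 0.22) were lower, U7 losing its call without replicate 3 of the wild type or replicate 1 of the ATG7-/- vesicles (-0.53 and -0.48, adjusted p = 0.079 in both).

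As lists, all snoRNAs with scaRNAs had a median of -1.69 in ATG7-/- vesicles (256 tested, 224 lower, 2 higher, 30 not called, list-alone 228 and 2, camera adjusted p = 5.24e-94, estimated adjusted p = 0.0112). C/D box snoRNAs stood at -1.44 (140 tested, 117 lower, 2 higher, list-alone 120 and 2, adjusted p = 1.11e-29, estimated adjusted p = 0.0728). H/ACA box snoRNAs stood at -1.96 (88 of 92 lower, 88 list-alone, adjusted p = 4.49e-28, estimated adjusted p = 0.0781). The scaRNAs stood at -1.51 (19 of 24 lower, 19 list-alone, adjusted p = 1.22e-06, estimated adjusted p = 0.0565). Host genes and function gave the same sign. The medians were, for GAS5, -1.42 (8 of 10 lower, adjusted p = 0.00025, estimated adjusted p = 0.149) and, for RPL13A, -1.81 (4 of 4, adjusted p = 0.00522, estimated adjusted p = 0.176). They were, for SNHG1, -1.55 (7 of 8, U22 higher, adjusted p = 0.00698, estimated adjusted p = 0.196) and, for cleavage snoRNAs, -1.24 (14 of 15, adjusted p = 2.65e-05, estimated adjusted p = 0.278), each with the same list-alone counts. Of the 15 cleavage snoRNAs 5 are copies of U3, here and in the other comparisons, and that list was not tested with U3 counted once.

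tRNA stood at 0.47 in ATG7-/- vesicles (467 tested, 241 higher, 6 lower, 220 not called, list-alone 237 and 6, adjusted p = 1.33e-45, estimated adjusted p = 0.0112), and at 0.09 in the scaling that lowered it most. Isotypes known for 5-prime fragments stood at 0.67 (107 of 144 higher, 108 list-alone, adjusted p = 3.65e-16, estimated adjusted p = 0.0781). Other isotypes stood at 0.37 (134 higher, 6 lower of 323, list-alone 129 and 6, adjusted p = 7.64e-12, estimated adjusted p = 0.0781). microRNAs (median 0.34, 37 higher, 11 lower of 113, list-alone 31 and 10, adjusted p = 0.105), let-7 (0.45, 4 of 7 higher, adjusted p = 0.261), and miR-17-92 (0.39, 5 of 11 higher, adjusted p = 0.228) were not called. Nor were serum and blood microRNAs (0.86, 2 of 3 higher, adjusted p = 0.293), Y RNAs (0.75, adjusted p = 0.225), vault RNAs (0.40, 1 of 3 higher, 3 list-alone, adjusted p = 0.225) and snRNAs (-0.44, adjusted p = 0.362). fry, which asks only whether a list moves on balance, gave an adjusted p of 2.51e-05 for C/D box snoRNAs, 2.51e-05 for H/ACA box snoRNAs and 0.000155 for tRNA. None of the list medians changed sign under the 5 scalings in this comparison, but that of other isotypes came down to 0.00034 with library totals and 0.0074 with TMM factors from microRNAs.

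**Figure D2:**
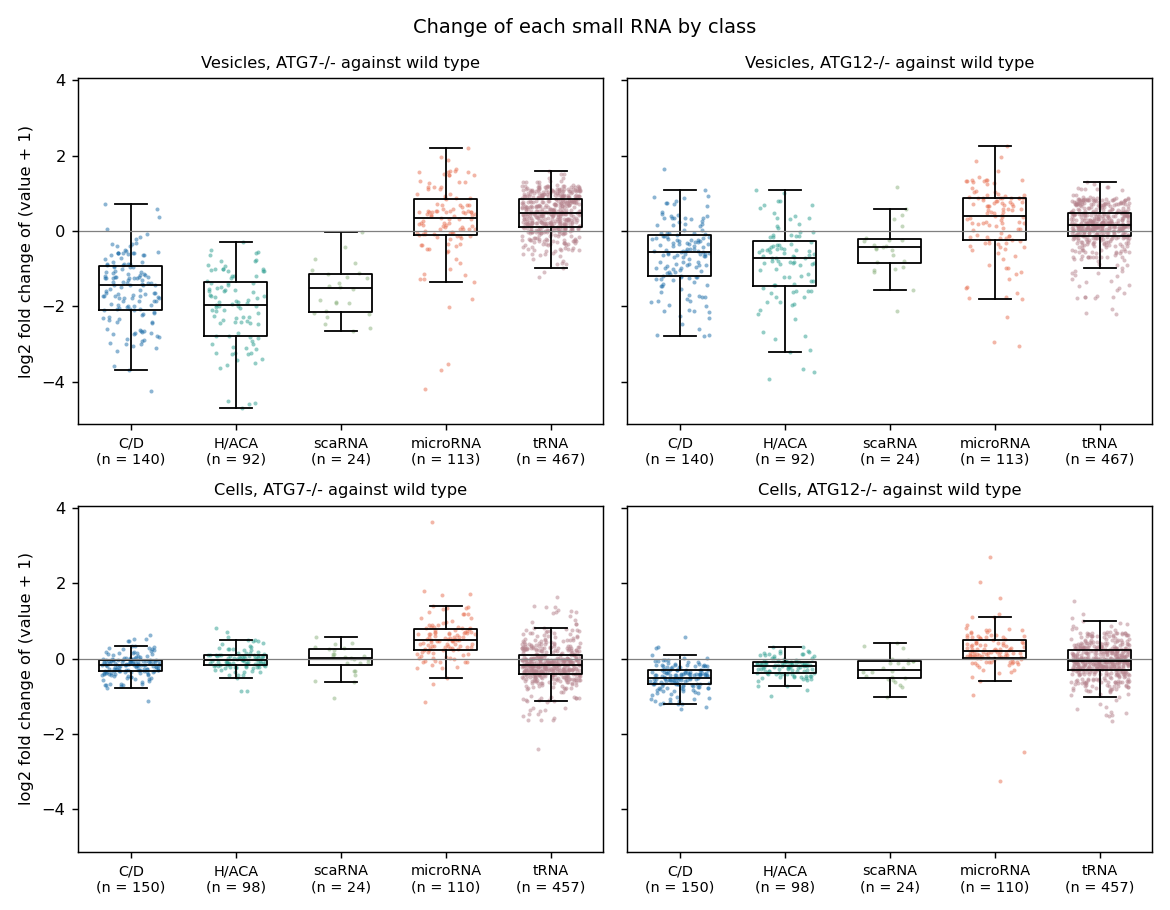
Log2 fold change of each tested small RNA (points) by class, knockout against wild type, in vesicles (top) and cells (bottom). Boxes span the quartiles, with the median as a line. Class medians in ATG7-/- vesicles were -1.44 for C/D box snoRNAs, -1.96 for H/ACA box snoRNAs and 0.47 for tRNA.

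In vesicles of ATG12-/- cells, 123 of 256 snoRNAs and scaRNAs were called lower and 17 higher, a list not called with an estimated correlation (adjusted p = 0.392). ACA28 changed by -3.92 (SE 0.21, adjusted p = 4.45e-08), from 579.6 ± 124 to 36.7 ± 1.61 normalised reads (SD, n = 3). U72 changed by -3.66 (SE 0.19), ACA62 by -3.22 (SE 0.18) and ACA16 by -3.16 (SE 0.34). miR-222-3p changed by -3.06 (SE 0.26, adjusted p = 4.15e-06) and U8, which guides processing of the large subunit RNAs, by -2.78 (SE 0.20). U22 rose by 1.66 (SE 0.18, adjusted p = 1.83e-05), from 3040 ± 414 to 9612 ± 1588 normalised reads.

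Of 850 features, 192 were higher in ATG12-/- vesicles, 179 were lower and 479 were not called, and the groups did not overlap for 448 (52.7%, 10% by chance). With library totals 22.2% of calls were higher and with TMM factors from microRNAs 15.5%, against 51.8%, with shifts of the median of all features of -0.35 and -0.38. Also lower were U94 (SNORD94, in PTCD3, -2.75, SE 0.30), ACA31 (in TPT1, -2.69, SE 0.21), U35A (-1.97, SE 0.23), U74 (-1.45, SE 0.15), U34 (-0.92, SE 0.14) and ACA10 (-0.84, SE 0.14). The scaRNAs U87 (SCARNA5, in an intron of ATG16L1, -2.11, SE 0.26) and U91 (-1.07, SE 0.19) were lower. U50 (in SNHG5, 0.93, SE 0.16), U76 (in GAS5, 0.87, SE 0.23) and ACA61 (in SNHG12, 0.81, SE 0.15) were higher, U76 not with library totals and neither U76 nor ACA61 with microRNA TMM factors. The snRNAs U6 (1.28, SE 0.16), U1 (0.71, SE 0.13) and U2 (0.59, SE 0.14) and the telomerase RNA (1.04, SE 0.19) were higher, U1 not with microRNA TMM factors and U2 with neither of those scalings. U5 (-1.24, SE 0.16) and U7 (-0.89, SE 0.22) were lower.

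let-7b-5p (1.98, SE 0.31), miR-486-5p (1.59, SE 0.21), miR-877-5p (1.44, SE 0.23), miR-937-3p (1.36, SE 0.31) and miR-150-5p (1.31, SE 0.25) were higher in ATG12-/- vesicles. miR-937-3p is 1 of 6 microRNA arms on chromosome 8 with nearly the same reads in each vesicle library, and each of the 6 is counted among the microRNAs. Also higher were let-7a-5p (0.89, SE 0.17), miR-92a-3p (0.88, SE 0.15) and miR-25-3p (0.80, SE 0.14), and miR-19b-3p (-1.14, SE 0.22) and miR-6724-5p (-0.90, SE 0.16) were lower. tRNA-Ser-AGA-2-6 (0.84, SE 0.09) and Glu-CTC-1-2 (0.71, SE 0.08, lost with microRNA TMM factors) rose. RNY3 (1.22, SE 0.12) and RNY1 (1.18, SE 0.13) were higher and RNY5 (-0.67, SE 0.12) lower, as in ATG7-/- vesicles. RNY4 (0.01, adjusted p = 0.949) was not called as deposited and was lower with library totals. VTRNA1-1 was higher (0.48, SE 0.13, adjusted p = 0.00836, lost under both of those scalings), and VTRNA1-2 (0.22, adjusted p = 0.19) was not called. VTRNA1-3 (0.33, adjusted p = 0.137) was called only without replicate 1 of the ATG12-/- vesicles (0.48, adjusted p = 0.0434).

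As lists in ATG12-/- vesicles, all snoRNAs with scaRNAs had a median of -0.60 (123 lower, 17 higher, 116 not called of 256, list-alone 130 and 17, adjusted p = 1.04e-19, estimated adjusted p = 0.392). C/D box snoRNAs stood at -0.57 (66 lower, 9 higher of 140, list-alone 69 and 9, adjusted p = 7.83e-10), and at 0.01 without a filter, where camera still placed them lower. The H/ACA box median was -0.72 (52 lower, 7 higher of 92, list-alone 54 and 8, adjusted p = 6.25e-10). The scaRNAs stood at -0.43 (5 lower, 1 higher of 24, adjusted p = 0.0322), with adjusted p = 0.0557 and 0.139 without replicate 1 of the wild type and replicate 2 of the ATG12-/- vesicles. RPL13A snoRNAs stood at -1.09 (4 of 4 lower, adjusted p = 0.00746). tRNA stood at 0.15 (133 higher, 40 lower of 467, list-alone 133 and 39, adjusted p = 2.94e-09), at -0.19 with library totals and at -0.22 with microRNA TMM factors. Isotypes known for 5-prime fragments stood at 0.41 (70 higher, 15 lower of 144, list-alone 72 and 15, adjusted p = 3.68e-06). For each of these 6 lists the estimated adjusted p was 0.392. Other isotypes (0.13, 63 higher, 25 lower of 323, list-alone 57 and 22, adjusted p = 0.00746) and microRNAs (0.40, 35 higher, 13 lower of 113, list-alone the same, adjusted p = 0.0453) had estimated adjusted p = 0.437. Other isotypes also changed sign with the scaling, and the microRNAs lost their call without replicate 2 or 3 of the wild type or replicate 1 of the ATG12-/- vesicles (medians 0.43, 0.37 and 0.40).

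Not called in ATG12-/- vesicles were the lists of GAS5 (-0.44, adjusted p = 0.0742), SNHG1 (-0.73, adjusted p = 0.0959), let-7 (0.72, adjusted p = 0.222) and miR-17-92 (0.30, adjusted p = 0.397, changing sign with the scaling). The same held for serum and blood microRNAs (1.31, adjusted p = 0.0742), Y RNAs (0.60, adjusted p = 0.286), vault RNAs (0.33, adjusted p = 0.226, also changing sign) and snRNAs (0.59, adjusted p = 0.286). The cleavage snoRNAs had a median of 0.34 and a mean of -0.08 (3 higher, 3 lower of 15, adjusted p = 0.854), and their median changed sign with the scaling.

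The 2 knockouts were compared directly in vesicles. The snoRNAs were higher in ATG12-/- than in ATG7-/- vesicles, the median of all snoRNAs with scaRNAs being 1.06 (197 higher, 59 not called of 256, 203 list-alone, adjusted p = 7.91e-66, estimated adjusted p = 0.0222). ACA61 was higher by 3.12 (SE 0.15, adjusted p = 2.17e-08), HBI-61 by 2.25 (SE 0.22), U50 by 2.15 (SE 0.16), HBII-420 by 2.05 (SE 0.20) and ACA40 by 1.99 (SE 0.18), n = 3 per group. miR-222-3p changed by -3.04 (SE 0.26) and tRNA-Ala-AGC-chr6-96 changed by -2.59 (SE 0.25).

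Of 850 features, 226 were higher in ATG12-/- than in ATG7-/- vesicles, 198 were lower and 426 were not called, and 499 had groups that did not overlap (58.7%, 10% by chance). TMM factors moved the median of all features by 0.13. The scaRNAs ACA66 (1.97, SE 0.29), U100 (1.88, SE 0.32) and ACA26 (1.85, SE 0.18) were higher. So were the snoRNAs U96a (1.91, SE 0.20), ACA25 (1.81, SE 0.23), ACA21 (1.65, SE 0.16), U3 (1.58, SE 0.16), U26 (1.57, SE 0.16) and U67 (1.54, SE 0.18), with hTR (1.31, SE 0.19), U2 (1.14, SE 0.14) and U1 (0.85, SE 0.13). tRNA-Ala-AGC-19-1 (-1.74, SE 0.29), Gln-CTG-1-4 (-1.02, SE 0.17) and Glu-CTC-1-2 (-0.47, SE 0.08), VTRNA1-2 (-0.51, SE 0.13), RNY4 (-0.40, SE 0.10, lost with microRNA TMM factors) and miR-19a-3p (-1.56, SE 0.38) were lower. miR-210-5p (-1.20, SE 0.43, adjusted p = 0.0349) lost its call with TMM factors, in 1 fit over all libraries, and without replicate 1 or 3 of the ATG7-/- or any of the ATG12-/- vesicles (-1.29 to -1.07, adjusted p = 0.0564 to 0.116). U3 fell from 118964 ± 26033 normalised reads in wild type vesicles to 50392 ± 10318 in ATG7-/- and stood at 149905 ± 18556 in ATG12-/- vesicles.

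As lists in that direct comparison, C/D box snoRNAs stood at 0.95 (98 of 140 higher, 101 list-alone, adjusted p = 5.99e-23, estimated adjusted p = 0.103). The H/ACA box median was 1.14 (81 of 92, 85 list-alone, adjusted p = 2.79e-23, estimated adjusted p = 0.106). The scaRNAs stood at 1.09 (18 of 24, 19 list-alone, adjusted p = 1.29e-06, estimated adjusted p = 0.0584). GAS5 snoRNAs stood at 1.15 (9 of 10, adjusted p = 3.99e-05, estimated adjusted p = 0.106). SNHG1 snoRNAs stood at 0.84 (5 of 8, adjusted p = 0.0092, estimated adjusted p = 0.207). Cleavage snoRNAs stood at 1.05 (14 of 15, adjusted p = 2.59e-07, estimated adjusted p = 0.207). tRNA stood at -0.26 (188 lower, 11 higher of 467, list-alone 181 and 9, adjusted p = 1.31e-45, estimated adjusted p = 0.0222). microRNAs had a median of 0.01 and a mean of -0.01 (adjusted p = 0.877), with a sign that changed with the scaling.

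Both knockout vesicle changes share the wild type vesicle libraries. Across 850 features their fold changes had r = 0.751, against 0.492 (0.380 to 0.606) in 100 simulations without any effect, and a covariance of 0.797 against 0.0362. The sign was the same for 77.9% of features, against 66.7% in the simulations. Lower in both were 136 features (51.8 for independent lists), higher in both 154 (64.4) and opposite 24 (116), and part of the excess may come from the shared controls, which are too few to split. The 136 held 65 C/D box snoRNAs, 52 H/ACA box snoRNAs and 5 scaRNAs, and the 154 held 127 tRNA genes and 22 microRNAs.

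**Figure D3:**
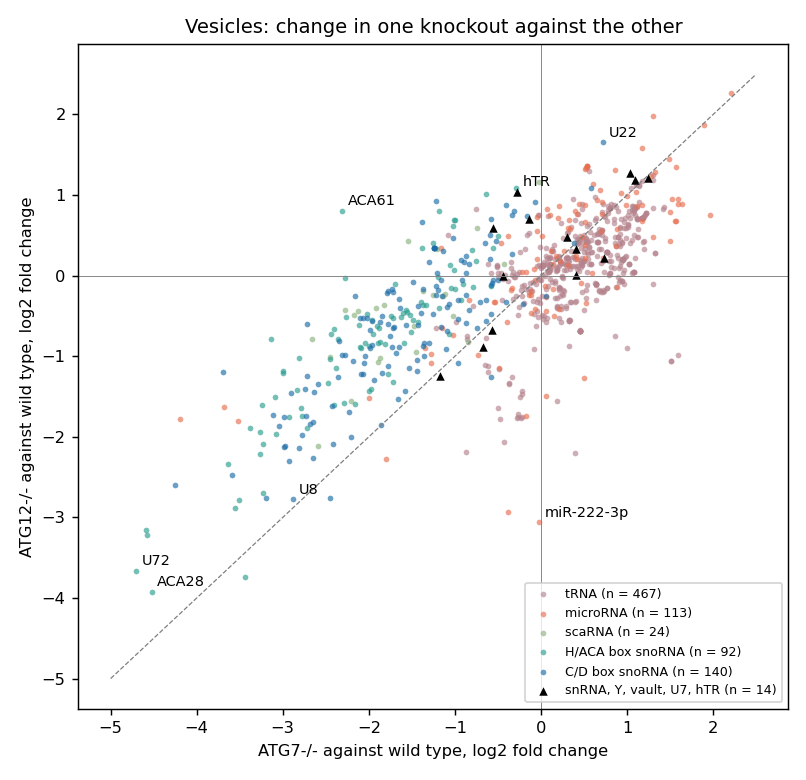
Log2 fold change against wild type vesicles of each small RNA in ATG7-/- vesicles (horizontal) and in ATG12-/- vesicles (vertical), by class. The dashed line marks equal change. Of all 140 C/D box snoRNAs, 98 tested higher in ATG12-/- than in ATG7-/- vesicles.

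Taking the mean of both knockouts against wild type vesicles, ACA28 changed by -4.22 (SE 0.18), U72 by -4.18 (SE 0.16), ACA62 by -3.90 (SE 0.15), U19 by -2.98 (SE 0.16) and U94 by -2.97 (SE 0.26). The comparison holds 6 knockout and 3 wild type libraries. Of 850 features 262 were higher, 241 lower and 347 not called, and 350 had groups that did not overlap (41.2%). With library totals 24.8% of calls were higher and with microRNA TMM factors 22%, against 52.1%. let-7b-5p (1.64, SE 0.27), miR-877-5p (1.47, SE 0.20), miR-342-3p (1.26, SE 0.19), miR-92a-3p (0.93, SE 0.13), RNY3 (1.23, SE 0.11), and RNY1 (1.14, SE 0.12) were higher. So were U22 (1.19, SE 0.15), U6 (1.16, SE 0.14), VTRNA1-2 (0.48, SE 0.11, lost with library totals and microRNA TMM factors), tRNA-Tyr-GTA-2-1 (1.24, SE 0.14) and tRNA-Ile-AAT-chr6-79 (1.13, SE 0.13). U5 (-1.21, SE 0.14), U7 (-0.78, SE 0.19), RNY5 (-0.62, SE 0.11), U3 (-0.44, SE 0.14, adjusted p = 0.0159) and ACA21 (-0.42, SE 0.14, adjusted p = 0.0207) were lower, the last pair not without replicate 1 of the wild type vesicles (both -0.27, adjusted p = 0.0929 and 0.0996). The means of U3 and ACA21 rest on ATG7-/- vesicles, since in ATG12-/- vesicles neither averaged below wild type. U1 was called higher as deposited (0.28, SE 0.11, adjusted p = 0.0434) and reversed with library totals and microRNA TMM factors. Its call was also lost with DESeq2, edgeR, TMM, the factors of the fitted libraries, no filter, the replicate block and 1 fit over all libraries, and without replicate 2 or 3 of any vesicle group (0.18 to 0.29, adjusted p = 0.0561 to 0.24). miR-6724-5p accounts for the fall of the microRNA share in knockout vesicles. It took 4.44% ± 0.614 in ATG7-/- and 6.11% ± 0.545 in ATG12-/- vesicles, and all other microRNAs 0.354% ± 0.0204 and 0.391% ± 0.00489.

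By class, reads in ATG7-/- vesicles were 7.12% ± 1.18 C/D box snoRNA, 0.708% ± 0.132 H/ACA box snoRNA and 80.02% ± 2.26 tRNA, and in ATG12-/- vesicles 21% ± 1.15, 1.92% ± 0.193 and 58.8% ± 2.15 (SD, n = 3). These shares count every tRNA gene. With each mature tRNA counted once, tRNA took 59.2% in ATG7-/-, 34.3% in ATG12-/- and 27.2% in wild type vesicles. The C/D box share was then 14.5%, 33.5% and 32.3% in turn, so in ATG12-/- it no longer lay below wild type. In the 6 knockout against the 3 wild type vesicle libraries, an exact permutation test over 10 classes gave adjusted p = 0.0397 for the microRNA share (5.65% against 15%), adjusted p = 0.0476 for tRNA (69.4% against 50.0%) and adjusted p = 0.0476 for H/ACA box snoRNAs (1.32% against 2.84%). The C/D box share (14.1% against 22.2%) gave an exact p of 0.143. As lists for the mean of both knockouts, all snoRNAs with scaRNAs stood at -1.16 (201 lower, 3 higher of 256, list-alone 204 and 4, adjusted p = 2.8e-62, estimated adjusted p = 0.0388). The C/D box median was -1.02 (107 lower, 2 higher of 140, list-alone 109 and 2, estimated adjusted p = 0.125). The H/ACA box median was -1.34 (76 of 92 lower, 77 lower and 1 higher adjusted over the list alone, estimated adjusted p = 0.133). The tRNAs stood at 0.30 (208 higher, 23 lower of 467, list-alone 203 and 21, adjusted p = 3.11e-29, estimated adjusted p = 0.0388), the tRNA median turning to -0.06 with library totals. microRNAs stood at 0.36 (44 higher, 14 lower of 113, list-alone the same, adjusted p = 0.0408, estimated adjusted p = 0.399) and at -0.01 in the lowest scaling. That call was lost without replicate 2 or 3 of the wild type or 1 or 3 of the ATG7-/- vesicles (0.32 to 0.37, adjusted p = 0.0506 to 0.153).

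In ATG7-/- cells, set against wild type cells to ask whether the vesicle changes follow the cells, 34 of 110 microRNAs were called higher and 75 were not called. Their median of 0.50 came down to -0.0022 with microRNA TMM factors, which hold most microRNAs near no change by construction and so cannot check this rise. miR-126-5p rose by 1.68 (SE 0.26), let-7b-5p by 1.38 (SE 0.16), miR-17-5p by 1.34 (SE 0.17), miR-19a-3p by 1.34 (SE 0.24) and miR-19b-3p by 1.18 (SE 0.21), with n = 3 per group. The vault RNAs moved apart, VTRNA1-1 by -1.04 (SE 0.21) and VTRNA1-2 by 1.19 (SE 0.20). tRNA-Asn-GTT-8-1 changed by -1.62 (SE 0.16).

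Of 853 features, 72 were higher in ATG7-/- cells, 71 were lower and 710 were not called, and 300 had groups that did not overlap (35.2%, 10% by chance). Without wild type replicate 1, 2 or 3 the 143 calls fell to 88, 74 and 77, and with microRNA TMM factors they rose to 560. Of the calls 50.3% were higher as deposited, 66.9% with DESeq2, 63.8% with its factors under the same test, 62.2% with library totals and 3.21% with microRNA TMM factors, which moved the median of all features by -0.53. let-7f-5p (0.89, SE 0.14), let-7a-5p (0.74, SE 0.13) and miR-92a-3p (0.62, SE 0.13) also rose, with tRNA-Lys-CTT-2-4 (1.21, SE 0.31), ACA31 (0.82, SE 0.15) and U102 (0.52, SE 0.14, reversed with microRNA TMM factors). Of these, let-7f-5p, let-7a-5p, miR-92a-3p, Lys-CTT-2-4 and ACA31 were not called with microRNA TMM factors. For the microRNAs among them that loss is no check, since those factors hold most microRNAs near no change. tRNA-Ala-AGC-12-3 (-1.36, SE 0.21), Asp-GTC-1-1 (-1.35, SE 0.29), SNORD121B (-1.13, SE 0.26), and U88 (SCARNA6, in ATG16L1, -1.03, SE 0.29) fell. So did U52 (-0.67, SE 0.15), U44 (-0.61, SE 0.16) and mgU2-25/61 (-0.59, SE 0.16), and SNORD121B, U102 and U88 were not called in 1 fit over all libraries. U88 was also lost with library totals and without a filter, and U44 without a filter. Calls were lost when single cell libraries were left out. For U88 these were each wild type library and ATG7-/- replicates 1 and 3 (-1.14 to -0.76, adjusted p = 0.0517 to 0.0956), and for U102 each wild type library (0.47 to 0.56, adjusted p = 0.057 to 0.11). For mgU2-25/61 they were wild type replicates 1 and 3 and ATG7-/- replicates 2 and 3 (-0.58 to -0.48, adjusted p = 0.0612 to 0.0809). For U44 they were wild type replicates 1 and 3 (-0.58, adjusted p = 0.069 and 0.0701) and for Lys-CTT-2-4 wild type replicate 3 (1.10, adjusted p = 0.0873). RNY1 (0.24, adjusted p = 0.291), RNY3 (0.28, adjusted p = 0.195), RNY4 (0.41, adjusted p = 0.108), RNY5 (0.16, adjusted p = 0.623) and VTRNA1-3 (0.14, adjusted p = 0.673) were not called by limma. DESeq2 and library totals gave calls for RNY3 and RNY4, and RNY3 was also called without ATG7-/- replicate 3 (0.41, adjusted p = 0.0246).

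As lists in ATG7-/- cells, microRNAs had a median of 0.50 (34 higher, 1 lower, 75 not called of 110, list-alone 41 and 2, adjusted p = 1.23e-19). The let-7 family stood at 0.79 (4 of 8 higher, 6 list-alone, adjusted p = 5.03e-06). The miR-17-92 group stood at 0.65 (9 of 15 higher, 11 list-alone, adjusted p = 1.51e-07), each with estimated adjusted p = 0.033. The microRNA median came down to 0.044 without a filter. It was -0.0022 with TMM factors taken from microRNAs themselves, a value near 0 by construction. C/D box snoRNAs stood at -0.17 (3 higher, 9 lower of 150, adjusted p = 0.017, estimated adjusted p = 0.779), a call lost without wild type replicate 1 or 3 or ATG7-/- replicate 3 (-0.17 to -0.07, adjusted p = 0.0556 to 0.629). Adjusted over the list alone limma called 0 of them, against 37 at an unadjusted p under 0.05 and 11 called by edgeR. GAS5 snoRNAs stood at -0.45 (1 of 10 lower, 7 list-alone, adjusted p = 0.017, estimated adjusted p = 0.733). The tRNAs stood at -0.17 (29 higher, 55 lower of 457, list-alone 30 and 62, adjusted p = 0.00118, estimated adjusted p = 0.733), a call lost without ATG7-/- replicate 1 (-0.16, adjusted p = 0.423). Isotypes known for 5-prime fragments stood at -0.27 (10 higher, 16 lower of 133, list-alone 11 and 22, adjusted p = 0.0198, estimated adjusted p = 0.733). H/ACA box snoRNAs (-0.04, test direction up, adjusted p = 0.446), scaRNAs (median 0.03, mean -0.03, adjusted p = 0.655), cleavage snoRNAs (-0.19, adjusted p = 0.0511), other tRNA isotypes (-0.13, adjusted p = 0.0681), and RPL13A (-0.21, adjusted p = 0.337) were not called. Nor were SNHG1 (-0.22, adjusted p = 0.337), Y RNAs (0.26, adjusted p = 0.0988), snRNAs (0.10, adjusted p = 0.778) and vault RNAs (0.14, adjusted p = 0.636). Without ATG7-/- replicate 3, H/ACA box snoRNAs (0.10, adjusted p = 0.0015) and Y RNAs (0.40, adjusted p = 0.0168) were called. The medians of H/ACA box snoRNAs, scaRNAs, snRNAs, Y and vault RNAs changed sign with the scaling.

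In ATG12-/- cells, 75 of 150 C/D box snoRNAs were called lower, a list not called with an estimated correlation (adjusted p = 0.282). miR-222-3p went from 116.8 ± 5.91 to 12.1 ± 5.05 normalised reads (SD, n = 3), a change of -3.25 (SE 0.27, adjusted p = 6.34e-06). let-7b-5p rose by 2.03 (SE 0.16) and let-7a-5p by 1.12 (SE 0.13). U45A changed by -1.33 (SE 0.22), HBII-115 (SNORD23) by -1.28 (SE 0.19), U7 by -1.25 (SE 0.13) and U22 by -1.20 (SE 0.26).

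Of 853 features, 64 were higher in ATG12-/- cells, 155 were lower and 634 were not called, and 414 had groups that did not overlap (48.5%, 10% by chance). Leaving out 1 library cut the 219 calls to 96 and 116 (wild type replicates 1 and 2) and to 119, 134 and 129 (ATG12-/- replicates 1, 2 and 3). The share of calls that were higher depended on the scaling: 29.2% as deposited, 49.3% with DESeq2, 52.8% with its factors under the same test, 52.2% with TMM, 44.2% with edgeR, 62.7% with library totals and 5.70% with microRNA TMM factors. The median of all features moved by 0.15, 0.14, 0.23 and -0.26 with the factors of the fitted libraries, TMM, library totals and microRNA TMM factors. U26 (-0.89, SE 0.18), U27 (-0.86, SE 0.15), U34 (-0.75, SE 0.15), U44 (-0.63, SE 0.16), U13 (-0.62, SE 0.16), and U8 (-0.59, SE 0.13) fell. So did U43 (-0.56, SE 0.15), the H/ACA box snoRNAs ACA10 (-0.56, SE 0.18, adjusted p = 0.0397) and U68 (-0.54, SE 0.17, adjusted p = 0.0357), U4 (-0.64, SE 0.12), VTRNA1-2 (-0.73, SE 0.20) and VTRNA1-3 (-0.61, SE 0.21, adjusted p = 0.0486). tRNA-Asp-GTC-2-11 (-1.66, SE 0.16) and Asn-GTT-10-1 (-1.43, SE 0.17) fell, and Gly-GCC-4-1 (1.52, SE 0.31), Ala-CGC-4-1 (0.95, SE 0.14), Glu-CTC-1-3 (0.66, SE 0.19), miR-196a-5p (0.78, SE 0.13), miR-17-5p (0.76, SE 0.17) and let-7f-5p (0.49, SE 0.14) rose. ACA10, U68 and VTRNA1-3 lost their calls with DESeq2, edgeR, library totals, TMM, the factors of the fitted libraries and no filter. VTRNA1-2 lost its call under those 3 scalings, U13 with library totals, U43 and U44 without a filter, Glu-CTC-1-3 without a filter and with microRNA TMM factors, and let-7f-5p with the latter. ACA10 also lost its call with the replicate block. ACA10 and U68 lost theirs without any 1 of the 6 libraries (-0.63 to -0.49 and -0.57 to -0.47, adjusted p = 0.0597 to 0.14 and 0.0738 to 0.128). Without wild type replicate 1 or ATG12-/- replicate 1, calls were lost for VTRNA1-3, VTRNA1-2, U13, U43, U44, let-7f-5p and Glu-CTC-1-3. Calls were also lost without wild type replicate 2 for VTRNA1-3, VTRNA1-2, U13 and let-7f-5p, and without wild type replicate 3 for U43, let-7f-5p and Glu-CTC-1-3. The same held without ATG12-/- replicate 2 for Glu-CTC-1-3 and replicate 3 for VTRNA1-3, U43 and let-7f-5p. Values without them were -0.67 to -0.42 for VTRNA1-3, -0.69 to -0.61 for VTRNA1-2, -0.62 to -0.61 for U13, -0.56 to -0.53 for U43 and -0.61 to -0.60 for U44. They were 0.41 to 0.56 for let-7f-5p and 0.54 to 0.70 for Glu-CTC-1-3, with adjusted p from 0.0509 to 0.187 over these 7.

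Not called by limma in ATG12-/- cells were VTRNA1-1 (-0.58, adjusted p = 0.0552) and the Y RNAs RNY1 (-0.01), RNY3 (0.27), RNY4 (0.03) and RNY5 (-0.53), with 1 Y RNA at an unadjusted p under 0.05. DESeq2 and 3 scalings gave a call for RNY3. VTRNA1-1 and RNY5 were called lower with microRNA TMM factors and in 1 fit over all libraries, VTRNA1-1 also at a minimum of 50 and RNY5 with the replicate block. VTRNA1-1 was called without wild type replicate 3 (-0.75, adjusted p = 0.0418) and RNY5 without ATG12-/- replicate 2 (-0.68, adjusted p = 0.0479).

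As lists in ATG12-/- cells, C/D box snoRNAs stood at -0.50 (75 of 150 lower, 92 list-alone, adjusted p = 2.88e-17, estimated adjusted p = 0.282), keeping that sign in all 5 scalings, and SNHG1 snoRNAs had a median of -0.76 (7 of 8 lower, adjusted p = 0.000523, estimated adjusted p = 0.282). GAS5 snoRNAs (-0.40, 4 of 10 lower, adjusted p = 0.0309, estimated adjusted p = 0.50) and cleavage snoRNAs (-0.20, 4 of 15 lower, adjusted p = 0.0409, estimated adjusted p = 0.611) were called with the preset correlation, the cleavage snoRNAs turning to 0.03 with library totals. microRNAs stood at 0.20 (17 higher, 2 lower of 110, list-alone 10 and 2, adjusted p = 1.37e-09, estimated adjusted p = 0.162). The let-7 family stood at a median of 0.17 and a mean of 0.54 (3 of 8 higher, adjusted p = 0.000523, estimated adjusted p = 0.162). The miR-17-92 group stood at 0.27 (2 of 15 higher, 1 list-alone, adjusted p = 0.00353, estimated adjusted p = 0.256). The medians of microRNAs and let-7 turned to -0.04 and -0.06 in the lowest scaling, with TMM factors from microRNAs. Those factors hold most microRNAs near no change by construction. tRNA had a median of -0.06 while camera placed it above the other features (47 higher, 56 lower of 457, list-alone 42 and 54, adjusted p = 0.00112, estimated adjusted p = 0.398), and its median ranged from -0.32 to 0.16 over the scalings. That call was lost without wild type replicate 3 (-0.10, adjusted p = 0.0801). Other tRNA isotypes went the same way (-0.05, 28 higher, 34 lower of 324, 17 and 17 list-alone, adjusted p = 0.00919, estimated adjusted p = 0.496), with a median from -0.31 to 0.17 over the scalings. H/ACA box snoRNAs (-0.19, 13 of 98 lower, 3 list-alone, adjusted p = 0.0739, changing sign with the scaling), scaRNAs (-0.29, adjusted p = 0.239) and RPL13A (-0.59, adjusted p = 0.0915) were not called. Without wild type replicate 1 or ATG12-/- replicate 1 or 3 the H/ACA box snoRNAs were (-0.24 to -0.21, adjusted p = 0.0197 to 0.0394). Also not called were isotypes known for 5-prime fragments (-0.10, adjusted p = 0.232), vault RNAs (-0.61, adjusted p = 0.0915), snRNAs (-0.19, adjusted p = 0.758) and Y RNAs (median 0.01, mean -0.06, adjusted p = 0.669). The medians of these isotypes, snRNAs and Y RNAs changed sign with the scaling.

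The change in vesicles was set against the change in cells in 1 fit over all 18 libraries. In ATG7-/-, 238 of 905 features had a higher change in vesicles than in cells, 260 a lower one and 407 were not called. The vesicle change lay below the cell change for U72 (-4.79, SE 0.31), ACA28 (-4.77, SE 0.26), U3 (-1.07, SE 0.26) and ACA21 (-1.07, SE 0.29). The median difference of C/D box snoRNAs was -1.28 (117 of 150 lower, 119 list-alone, estimated adjusted p = 0.0454) and that of H/ACA box snoRNAs -1.88 (87 of 98 lower, 88 list-alone, estimated adjusted p = 0.0494). tRNA had a median difference of 0.64 (228 higher, 17 lower of 489, list-alone 225 and 16, estimated adjusted p = 0.000128), led by Gly-CCC-2-2 (1.93, SE 0.18). In ATG12-/-, 130 features had a higher change in vesicles than in cells, 109 a lower one and 666 were not called. It lay below the cell change for ACA28 (-4.04, SE 0.26), U72 (-3.55, SE 0.31) and U8 (-2.19, SE 0.25) and above it for U22 (2.85, SE 0.34). C/D box snoRNAs as a list had a median difference of -0.02 (17 higher, 33 lower of 150, list-alone 19 and 33, adjusted p = 0.0753), changing sign with the scaling. It was called lower without wild type replicates 2 or 3 of the vesicles or 1 or 3 of the cells (-0.09 to -0.02, adjusted p = 0.0143 to 0.0411). H/ACA box snoRNAs had one of -0.48 (35 lower, 10 higher of 98, list-alone 38 and 10, adjusted p = 2.47e-08, estimated adjusted p = 0.531). The share of calls that were higher moved from 47.8% in ATG7-/- to 17.9% with library totals, 34.5% with TMM, 33.5% with edgeR and 62.7% with microRNA TMM factors, with shifts of the median of -0.46, -0.26 and 0.37 for library totals, TMM and microRNA TMM factors. In ATG12-/- it moved from 54.4% to 6.94% with library totals, 21.2% with TMM and 27.5% with edgeR, with shifts of -0.58 and -0.31 for library totals and TMM.

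**Figure D4:**
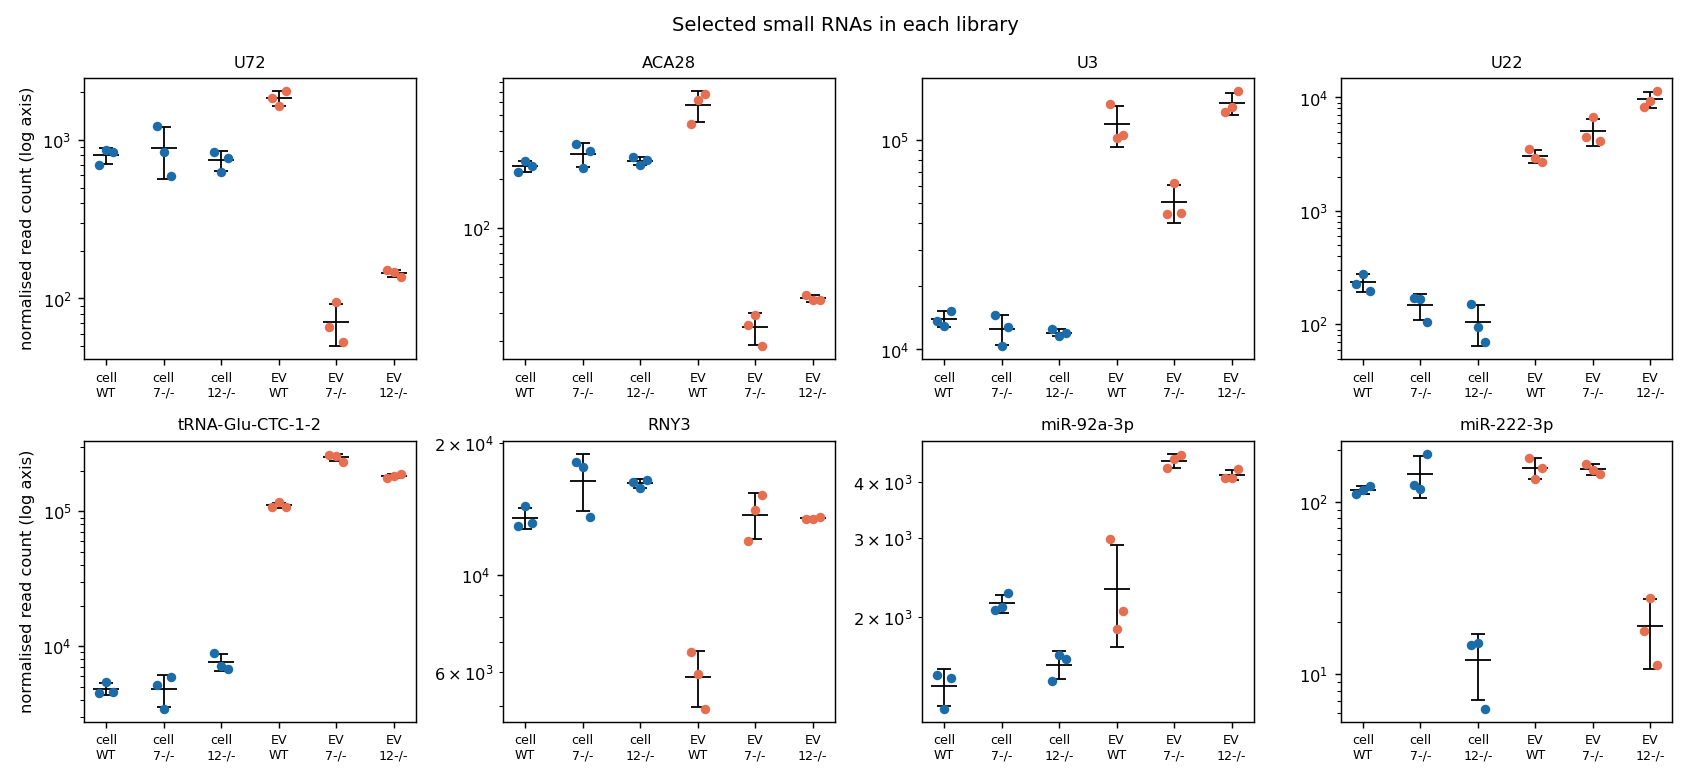
Normalised reads (log axis) of 8 small RNAs in each library, with the mean and SD of each group of 3 (cells blue, vesicles orange). U72 averaged 1839 in wild type vesicles, 71.2 in ATG7-/- and 144.0 in ATG12-/- vesicles.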

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

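Chosen after the result was seen were all tests of explanations except those of carry-over from the cells, length in H/ACA box snoRNAs, GC content and tRNA copies counted once. The counts of other splits, counting U3 once, and the requirement that an interval as well as its value lie beyond a bound, were also chosen then.

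The change of some small RNAs differed between vesicles and cells, found by a test of the difference itself (vesicle change minus cell change). In ATG7-/-, 498 features differed. The median differences were -1.28 for C/D box snoRNAs (estimated adjusted p = 0.0454), -1.88 for H/ACA box snoRNAs (0.0494), -1.49 for scaRNAs (0.0585) and 0.64 for tRNA (0.000128). The change in vesicles lay below the change in cells for U72 (-4.79, SE 0.31), ACA28 (-4.77, SE 0.26), miR-19b-3p (-1.67, SE 0.33), U5 (-1.27, SE 0.24), U3 (-1.07, SE 0.26) and ACA21 (-1.07, SE 0.29). It lay above for tRNA-Gly-CCC-2-2 (1.93, SE 0.18), VTRNA1-1 (1.35, SE 0.26), tRNA-Glu-CTC-1-2 (1.22, SE 0.25), RNY3 (0.96, SE 0.21) and U6 (0.93, SE 0.25). RNY3 and U6 were not called with library totals, nor ACA21 with TMM factors from microRNAs. None of the 11 lost its call when 1 library was left out.

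In ATG12-/-, 239 features differed in the same test. The median difference was -0.48 for H/ACA box snoRNAs and 0.23 for tRNA, each with adjusted p = 0.531 when the correlation was estimated. The tRNA difference turned to -0.08 with TMM and -0.34 with library totals, and its call was lost without wild type vesicle replicate 1 (0.20, adjusted p = 0.0715). The change in vesicles lay below that in cells for ACA28 (-4.04, SE 0.26), U72 (-3.55, SE 0.31), U8 (-2.19, SE 0.25) and miR-19b-3p (-1.50, SE 0.33). It lay above for U22 (2.85, SE 0.34), hTR (1.49, SE 0.28), tRNA-Val-CAC-1-4 (1.49, SE 0.23), U76 (1.31, SE 0.32) and RNY1 (1.19, SE 0.23). The same held for VTRNA1-1 (1.06, SE 0.26), miR-92a-3p (0.71, SE 0.21) and U44 (0.58, SE 0.20, adjusted p = 0.0362). With library totals the calls of U76, VTRNA1-1 and miR-92a-3p were lost and U44 reversed, and miR-92a-3p was not called with TMM or edgeR. U44 was also lost under 4 other alternatives and without vesicle replicates 2 or 3 of the wild type, any ATG12-/- vesicle library, or replicates 1 or 3 of either group of cells (0.51 to 0.61, adjusted p = 0.055 to 0.0983).

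Splits of the libraries within vesicles and within cells stand for no effect in either. They cannot tell a difference between the vesicle and cell changes from a change in 1 of them alone, so they do not decide these counts. In ATG7-/-, 1 of 100 splits called as many features, the real one with 498 against 473 for the next. In ATG12-/-, 4 of 100 did, the real count being 239 and the highest other 384. That highest split swapped the vesicle labels whole and kept the cell labels, so it holds the same structure of the samples. For the mean of both knockouts, 2 of 100 splits called as many as the real 503, a share under 0.05, and 1 called 518. It exchanged all ATG7-/- with all wild type vesicles, which again is the structure of the samples.

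The other comparisons set 3 libraries against 3, where 10 splits are too few for a share under 0.05. In each, 1 split, the real one, reached the real count. That count was 531 for ATG7-/- and 371 for ATG12-/- against wild type vesicles, and 424 between the knockout vesicles. It was 143 for ATG7-/- and 219 for ATG12-/- against wild type cells, and 740 for wild type vesicles against cells. The highest other split called 0 in all 6 with limma.

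The list of snoRNAs with scaRNAs was lower in ATG7-/- vesicles and less so in ATG12-/- vesicles, where 123 of 256 were called lower and 17 higher and the list was not called with an estimated correlation (adjusted p = 0.392). In ATG7-/- the list's median lay between -2.04 and -1.69 over 5 scalings, which argues against the choice among these scalings. All 5 rest on relative reads, so a change in the amount of other RNAs stays open. The vesicle change minus the cell change lay between -1.95 and -1.18, which argues against a fall of the same size in the cells. For RNA length, 43 C/D box snoRNAs were compared with 7 Y and vault RNAs, all of 84 to 113 nt by annotated gene length. No H/ACA box snoRNA or scaRNA with an annotated length fell in that range, so neither class was covered. The difference of medians was -1.71 (-1.30 against 0.41, permutation p = 0.00015, over RNAs). C/D box snoRNAs thus changed differently from Y and vault RNAs of similar length, but an effect of length within a class was not tested. In ATG12-/- a fall carried over from the cells stays open for C/D box snoRNAs. Their median vesicle change minus cell change was -0.02 (camera adjusted p = 0.0753), near what a fall of the same size in the cells would give. Between the vesicle and cell changes of 140 members rho was 0.193 (bootstrap 0.00631 to 0.361, permutation p = 0.0231). That lies under the bound of 0.2 as a value but not over its interval. A difference between genotypes stays open and untested, since each knockout is 1 clone and genotype and clone cannot be told apart.

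Length went with a higher level in wild type vesicles than in cells across C/D box snoRNAs, a trend carried by few genes. Across 149 genes rho was 0.237 (bootstrap 0.0570 to 0.398, permutation p = 0.00353), and it was 0.0958 without the 10 genes over 140 nt, 0.177 without the 14 of 101 to 130 nt, 0.208 without the 2 between these ranges and -0.0462 without all 3 groups. Of those 10 genes 5 are copies of U3, and with U3 counted once rho was 0.172 (-0.0017 to 0.339, permutation p = 0.0383). Across 97 H/ACA box snoRNAs rho was 0.0234 (-0.191 to 0.228, permutation p = 0.82), under the bound of 0.1 as a value but not over its interval, so length stays open for both. GC content went with the vesicle to cell change of 131 C/D box snoRNAs (rho 0.390, 0.225 to 0.524, permutation p = 1e-05, the smallest possible, and 0.348 with U3 counted once), so a bias by base composition may contribute, and no biological explanation was tested.

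Of 467 tRNA genes, 241 were called higher and 6 lower in ATG7-/- vesicles, and 133 higher and 40 lower in ATG12-/- vesicles, where the list was not called with an estimated correlation (adjusted p = 0.392). Reads shared between genes named as copies of the same mature tRNA do not account for the rise in ATG7-/-. There the median over 304 mature tRNAs counted once was 0.41. Reads shared between different tRNAs of similar sequence were not tested and stay open. The scaling of the libraries stays open in ATG7-/-, where the median ranged from 0.092 to 0.47 over 5 scalings. In ATG12-/- it ranged from -0.22 to 0.16, so the scaling may produce the rise. A difference between genotypes is open in both and was not tested apart from the clone.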

How the results depend on the processing

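Chosen after the data were seen were TMM factors under the main test, the 2 pseudocounts and each mature tRNA counted once. The edgeR test with TMM factors was the main test planned beforehand and became an alternative after the data were seen. Every alternative fixed before the data were examined was run. Among alternatives for the class medians, counts and shares that answer a comparison, 312 stayed and 12 lost a call. A further 4 gained one and 19 moved further. A count stayed when within a fixed ratio of the reported one, and a list when camera kept its direction and call. List medians that changed sign while camera did not are therefore among those that stayed. An example is the tRNA median of ATG12-/- vesicles (0.15 as reported, -0.22 with TMM factors from microRNAs). For the features named in the text, 4676 kept direction and side, 167 lost a call, 27 gained one, 36 moved and 11 reversed. For the other list medians, 828 stayed, 40 lost a call, 18 gained one and 23 moved, and for the other class shares 147 stayed and 13 moved. Each feature is counted once per alternative. Over the 602 feature and comparison pairs the rule picked there were 24 reversals and 881 lost calls counted in this way, against 11 reversals for the 266 named.

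Over its alternatives, ATG7-/- vesicles gave 284 to 576 calls, medians of -1.81 to -0.57 for C/D box snoRNAs, -2.32 to -1.87 for H/ACA box snoRNAs and 0.09 to 0.54 for tRNA. ATG12-/- vesicles gave 201 to 412 calls, -0.95 to 0.01 for C/D box snoRNAs (0.01 without a filter, while camera still placed them lower), -1.10 to -0.62 for H/ACA box snoRNAs and -0.22 to 0.21 for tRNA.

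With copies of 1 RNA summed, fewer features are tested by construction. The calls were 284 for ATG7-/- vesicles (531 as reported), 201 for ATG12-/- vesicles (371), 275 for their mean (503) and 217 between the knockouts (424). They were 57 for ATG7-/- cells (143), 124 for ATG12-/- cells (219), 323 for wild type vesicles against cells (740), and 244 and 135 for the vesicle change minus the cell change in ATG7-/- (498) and ATG12-/- (239). For the changes that follow the cause was not tested. TMM factors from microRNAs alone called 560 features in ATG7-/- cells. With each mature tRNA counted once, the microRNA share fell by 11.8 percent of reads in knockout vesicles (-9.40 as reported).

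The microRNA median in ATG7-/- vesicles, not called as reported, passed the threshold with library totals (0.012, adjusted p = 0.0101), TMM factors from microRNAs (0.019, adjusted p = 0.00554), 1 fit over all 18 libraries (0.32, adjusted p = 0.0257) and without wild type vesicle replicate 1 (0.43, adjusted p = 0.0246). Leaving out 1 library gave 0.28 to 0.43, and adjusted p over all alternatives was 0.00554 to 0.478. In ATG12-/- vesicles the microRNA call was lost without a filter (0, adjusted p = 0.373), at a minimum of 50 (0.58, adjusted p = 0.0891), with TMM (0.41, adjusted p = 0.0821) and with an estimated correlation (0.40, adjusted p = 0.437). It was also lost without wild type replicate 2 (0.43, adjusted p = 0.12) or 3 (0.37, adjusted p = 0.064) or ATG12-/- replicate 1 (0.40, adjusted p = 0.0552). Leaving out 1 library gave 0.37 to 0.50, and adjusted p over all alternatives was 4.50e-05 to 0.437.

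With the correlation estimated, the calls of C/D box (-1.44, adjusted p = 0.0728) and H/ACA box snoRNAs (-1.96, adjusted p = 0.0781) in ATG7-/- vesicles were lost, with adjusted p over their alternatives of 9.72e-32 to 0.0728 and 3.09e-57 to 0.0781. In ATG12-/- vesicles those of C/D box (-0.57), H/ACA box (-0.72) and tRNA (0.15) were lost, each at adjusted p = 0.392, with lowest values of 7.46e-12, 9.39e-19 and 1.90e-12.

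With library totals the sign reversed for RNY4 in ATG12-/- vesicles (-0.35, adjusted p = 0.039), U1 in the mean of both knockouts (-0.084) and U44 in the vesicle change minus the cell change of ATG12-/- (-0.0023). In wild type vesicles against cells it did so for ACA21 (-0.57), U6 (-0.035), U5 (-0.019), U2 (-0.85), miR-92a-3p (-0.82) and RNY4 (-0.21). With TMM factors from microRNAs it reversed for U1 in the mean of both knockouts (-0.10) and U102 in ATG7-/- cells (-0.013).

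Leaving out 1 library gave 74 to 158 calls in ATG7-/- cells, with 88, 74 and 77 without wild type replicates 1, 2 and 3. In ATG12-/- cells it gave 96 to 150, with 96 and 116 without wild type replicates 1 and 2 and 119, 134 and 129 without ATG12-/- replicates 1, 2 and 3. Fewer libraries lower the power by construction. The replicate block gave 523, 351, 483 and 374 calls for ATG7-/- vesicles, ATG12-/- vesicles, their mean and the knockouts against each other, 123 and 194 in cells, 739 in wild type and 494 and 229 for the vesicle change minus the cell change. Same-numbered libraries did not correlate best throughout. They did for each number in wild type against ATG12-/- vesicles (0.144, 0.0907 and 0.0947), so whether the numbers pair libraries stays open.

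At the depth of these libraries, in simulated reads with balanced and independent changes, 46.3% of 1.5-fold changes in ATG7-/- vesicles were recovered and 97.0% of 4-fold changes. Recovery was not tested at other depths. microRNAs other than miR-6724-5p took 0.335% of reads in wild type vesicles, and 113 microRNAs reached the level needed for a test in vesicles.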

Other observations

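Chosen after the data were seen were the groups of tRNA genes by isotype and the features singled out here, and no explanation of them was tested.

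miR-221-3p and miR-222-3p, both in MIR222HG on chromosome X, were lower in ATG12-/- cells (-2.48, SE 0.29 and -3.25, SE 0.27) and in ATG12-/- vesicles (-2.93, SE 0.29 and -3.06, SE 0.26). The vesicle change did not differ from the cell change past the threshold (-0.45, adjusted p = 0.444 and 0.19, adjusted p = 0.762). In ATG7-/- they were not called in vesicles (-0.38, adjusted p = 0.276 and -0.02, adjusted p = 0.954) or cells (0.46, adjusted p = 0.266 and 0.27, adjusted p = 0.513). Whether the fall belongs to the genotype or to the clone was not tested.

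The 6 arms of miR-937, miR-6845 and miR-4664, on chromosome 8 between 143733083 and 143837816, had reads that differed by at most 3 within any vesicle library. They held 57 to 239 reads in vesicle libraries and at most 3 in cell libraries. Whether they are 1 RNA entered 6 times among the 113 microRNAs tested in vesicles was not tested.

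Isotypes of tRNA were not tested against each other. Median changes in knockout vesicles were, for ATG7-/- and ATG12-/- in turn, 1.18 (23 of 26 genes higher) and 0.61 (19) for Glu, 0.80 (27 of 33) and 0.61 (18) for Gly, and 1.06 (9 of 12) and 1.12 (9) for Tyr. tRNA-His genes were higher in ATG7-/- vesicles (9 of 10, median 0.45, adjusted p = 0.0349) and lower in ATG12-/- vesicles (10 of 10, median -0.69, adjusted p = 0.00014). tRNA copies hold nearly the same reads, so counts and p-values may repeat 1 RNA. Estimated adjusted p was 0.513 to 0.738 for these 4. Isotypes were examined as deposited only, and the tRNA median was 0.092 (ATG7-/-) and -0.22 (ATG12-/-) in the lowest scaling.

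U22 was called higher in both knockout vesicles, in ATG7-/- not with library totals or TMM factors from microRNAs. The SNHG1 list that holds it was lower in ATG7-/- vesicles with the preset correlation and not called with an estimated one (adjusted p = 0.196). U87 and U88 lie in introns of ATG16L1, which encodes the partner of the ATG12 conjugate. U87 fell in ATG12-/- vesicles (-2.11, SE 0.26) and U88 in ATG7-/- cells (-1.03, SE 0.29), where its call was lost without any wild type cell library or ATG7-/- replicate 1 or 3 (-1.14 to -0.76).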
